A study of Mus musculus with 6 samples.

How the data were processed

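RNA of whole mouse uterus was measured on 6 Affymetrix arrays, 1 per time: 0 h (no injection) and 6, 12, 15, 18 and 24 h after 0.2 mg progesterone. Each array held 1 RNA sample pooled from 8 uterine horns of 4 ovariectomized mice, and groups and times were taken from the sample titles. Per the labels, RNA preparation, labelling of cRNA and hybridization followed the array maker's recommendations. The deposited values are log2 expression per probe set. The base was read from the values: of 2 raised to values under 2000 on the linear scale, 99.76% had 4 decimals within 0.05 of a unit of the 4th decimal, against 6.418% for the natural base. All 6 columns share a lower limit of 5.39 (42.0 on the linear scale), at which 21.1% to 22.5% of values per array lie. The software, background correction and normalization behind the values are not given in the sources used here, and a shared lower limit compresses differences of weakly expressed genes. The table held 12487 probe sets, of which 65 were controls and were left out, and 121 values of 108 probe sets were missing and stayed so.

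Scaling followed a rule fixed, like all lists, tests and thresholds unless stated otherwise, before the data were examined. The 2% trimmed means of the 6 columns lay between -4.10% and 3.42% of their median, within the 5% set for taking the table as already scaled, so values were used as deposited. Values below the 40th percentile of all values (6.60, or 96.9 on the linear scale) were set to that floor. This makes a difference from a floored value a limit rather than a size. Equal floored values also narrow the spread between arrays that the tests use, so p-values of such genes can be too small. Analysed were the 7731 probe sets above the floor on at least 2 of the 6 arrays, of which 6808 were above it on all 6. Gene names came from the platform annotation matched to the table. Of the 12422 probe sets that were not controls, 10833 had 1 gene symbol, 396 several and 1193 none; 10817 of those with 1 symbol were matched to current gene identifiers, which changed 0 symbols. Only probe sets with 1 symbol were named, 6971 of those analysed, for 5915 genes. Of 918 genes with several analysed probe sets, 17 had a median of at least 2-fold on 1 probe set and under 1.5-fold in that direction on another, so a gene's value is that of the probe set named first, and other probe sets are given where they differ.

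Each progesterone array was compared with the 0 h array by the log2 difference, counted at 2-fold, and probe sets were placed in sustained (2-fold in 1 direction at all 5 times), early (2-fold at 6 h, under 1.5-fold at 18 and 24 h) and late (under 1.5-fold at 6 h, 2-fold in 1 direction at 18 and 24 h) groups. With 1 array per time these have no test. Counts in 100 simulated sets of unchanged arrays with 1 shared reference stand beside them. Their spread per level came from the differences between 12 and 15 h, 15 and 18 h, and 18 and 24 h. The pair of 6 and 12 h was left out, so the simulated counts may be too low. Its log2 differences had an SD of 0.26, against 0.17 to 0.2 for the pairs used. The simulated 0 h array was given this spread too, while the real one differed from the progesterone arrays with an SD of 0.38 to 0.44. The simulation therefore cannot show a difference of the single 0 h array that has another cause than progesterone. To test the group, limma (lmFit and eBayes with an intensity trend) compared the 5 progesterone arrays with the 0 h array. In a separate fit limma took hours after injection as a number. For the 7672 analysed probe sets with a value on every array, each limma fit used all 6 arrays with 4 residual degrees of freedom. The 59 with missing values had 1 to 3; of these, 2 were called against 0 h, among them Mcm5 with 1, and Col5a2 was called in the trend with 3. Benjamini-Hochberg adjustment ran over the probe sets tested; "rose" and "fell" mark an adjusted p under 0.05 in one of these fits. Each other array was also put in the lone place of 0 h, and the times were put in 100 orders with the real one, drawn with repeats. A further 100 distinct orders kept the 0 h array first, a test added after the results were seen.

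For 30 gene lists, 19 of pathways or responses and 11 of cell types, the median difference from 0 h was taken with 1 probe set per gene, the one with the highest mean. It was placed among 10000 random lists of the same size matched on mean expression in 20 levels; a list needed 5 analysed genes. The lists were progesterone targets, steroid-responsive genes shared with glucocorticoids, estrogen-responsive genes, hedgehog, G1/S and DNA replication, mitosis, immediate-early genes, circadian clock, cholesterol and fatty acid synthesis, retinoid, steroid and prostaglandin metabolism, endoplasmic reticulum chaperones and heat shock, interferon-stimulated genes, chemokines, cytokines and complement, extracellular matrix, WNT, BMP and TGF-beta, oxidative phosphorylation and TCA cycle, cytosolic ribosomal proteins, ribosome biogenesis and transport. The cell type lists were uterine epithelium, stroma, smooth muscle, endothelium, macrophage, granulocyte and mast cell, lymphocyte, adipocyte, red blood cell, ovary with oviduct and mesothelium, and skeletal muscle. Counts of list genes that passed limma use this 1 probe set per gene, so a call on another probe set of a gene is not in them. Counts adjusted over the list alone repeat the Benjamini-Hochberg adjustment within a list.

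Genes were named by a fixed rule: the 8 highest and 8 lowest sustained genes above the floor on all arrays; the 4 highest and 4 lowest at each time; the 4 largest of the early and late groups in each direction; the 4 smallest adjusted p per direction in each limma fit; progesterone targets at least 2-fold from 0 h at any time, with Pgr, Esr1, Ihh, Areg, Ltf, Hoxa10 and Fkbp5 whatever their value; and up to 4 members of each list with the largest absolute median. Further list members are named where a limma call, a count of 5 or fewer or a contrast within the list was described; these, and genes said to be chosen after their values were seen, fall outside the rule.

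The alternatives were quantile and median scaling, floors at the 20th and 60th percentile, no filter or a filter on all 6 arrays, a 3-fold threshold, eBayes without trend, hours as log2(hours + 1) or as ranks, the trend without the 0 h array, each array left out, a mean over probe sets per gene, and the mean of the other 5 arrays as reference. Early and late groups without the 0 h array and the epithelium list without shared genes were added after seeing the data. The steps were tested on simulated data with 200 changed among 7731 probe sets in 5 runs. Simulated changes were equal at all 5 progesterone times, or linear for the trend, with the spread of the simulation above. Real genes vary between times, so recovery in these data may be lower. Against 0 h, 87.0% of changes of 1 log2 unit and 95.3% of changes of 2 were recovered, with 14.6 and 16.2 false calls per run. For the trend 83.4% and 86.6% were recovered with 5 and 4.4 false calls, and for the sustained group 82.7% and 82.8% at sizes of 2 and 4 with 0.6 false members. In unchanged data 10 of 150 list medians fell outside the central 95% of random lists, and a list of 18 genes shifted by 0.3 lay at percentile 100. The simulation drew each probe set on its own, so it cannot give the false rate for lists whose genes move together. The percentiles make no allowance for this either. The 5 times of a list share the 0 h array and are not separate results. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used. No genome was used here, and no coordinates are given.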

Results

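Gene expression was measured in whole uterine horns of ovariectomized 129/SvImJ wildtype female mice aged 10 to 16 weeks, an inbred strain whose own ovarian hormones had been removed by surgery. RNA was taken 14 days after ovariectomy from uninjected mice, called 0 h here, and 6, 12, 15, 18 and 24 h after a subcutaneous injection of 0.2 mg progesterone in 0.1 mL sesame oil. Each RNA sample pooled 8 horns of 4 mice and was hybridized to 1 Affymetrix array, so there were 6 arrays in 6 groups with no replicates, and their number limits the precision of every value. The design follows the response of the uterus to 1 dose of progesterone, a steroid hormone that acts through the receptor Pgr, over the first 24 h. No array of mice injected with oil alone was analysed here, the time of day of collection is not given in the sources used here, and every difference from 0 h rests on the same single 0 h array. The median log2 value per array lay between 7.12 and 7.22, and 7361 to 7557 probe sets per array were above the floor of 6.60. Values below are log2 expression, and differences are those of a progesterone array from the 0 h array.

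The first comparison asked which genes stood apart from 0 h on the 5 progesterone arrays as a group. Acot7, an acyl-CoA thioesterase, rose by 4.10 ± 0.17 (SE; mean of the 5 progesterone arrays minus 0 h, adjusted p = 8.1e-05), with differences between 3.90 and 4.34 at the single times. Lrp2, the endocytic receptor megalin, rose by 3.01 ± 0.20 (adjusted p = 0.00057). Npl, a sialic acid lyase, was at the floor at 0 h and rose by at least 3.37 at each time (adjusted p = 0.00057). Mthfd2, a mitochondrial enzyme of folate metabolism, rose by 2.77 ± 0.43 (adjusted p = 0.023), and Pla2g10, a secreted phospholipase A2, by 2.69 ± 0.31 (adjusted p = 0.0081). Acta1, the actin of skeletal muscle, rose by 2.30 ± 0.27 (adjusted p = 0.0081), and Nde1, a partner of the dynein motor, by 2.07 ± 0.24 (adjusted p = 0.0083). The median of Nde1 was 2.20, or 1.41 with the floor at the 60th percentile. Hdc, the enzyme that makes histamine, rose by 1.59 ± 0.20 (adjusted p = 0.0096). Sec23b, a coat protein of vesicles leaving the endoplasmic reticulum, rose by 2.21 ± 0.14 (adjusted p = 0.00057), and Gstm2, a glutathione transferase, by 2.15 ± 0.24 (adjusted p = 0.008). A different probe set of each of these last genes gave a median difference of 0.13 for Sec23b and 0.10 for Gstm2. Igf1, a growth factor, rose by 1.87 ± 0.24 (adjusted p = 0.01), with a median of 0.08 on its other probe set. Slc2a3, a glucose transporter, and Atp1b1, a sodium pump subunit, rose by 1.83 ± 0.31 (adjusted p = 0.029) and 1.75 ± 0.36 (adjusted p = 0.046). With the floor at the 60th percentile the medians of Acot7, Lrp2, Npl, Mthfd2 and Pla2g10 were lower too. They went from 4.13, 3.05, 3.59, 3.04 and 2.44 to 3.52, 2.25, 2.49, 2.09 and 2.06. Apart from Nde1, the other genes of this paragraph kept their medians.

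Among the genes that fell, Tgfbi, a secreted protein of the extracellular matrix, had a difference of -2.53 ± 0.50 (adjusted p = 0.042) and moved from -1.48 at 6 h to -2.96 at 24 h. Igfbp3, which binds insulin-like growth factors, fell on both of its probe sets, by 1.93 ± 0.32 and by 1.61 ± 0.27 (adjusted p = 0.027 and 0.029). Smpdl3a, a phosphodiesterase, fell by 1.73 ± 0.29, Ncam1, a cell adhesion molecule, by 1.63 ± 0.28, and Ltf, the estrogen-induced secreted protein lactoferrin, by 1.58 ± 0.29 (adjusted p = 0.029, 0.029 and 0.035). Abca4, a lipid transporter, fell by 1.59 ± 0.17 (adjusted p = 0.0061), and Lifr, the receptor for leukemia inhibitory factor, fell too, with differences of -1.33 at 6 h and -1.63 at 15 h (adjusted p = 0.0035). Efnb2, an ephrin, fell by 1.45 ± 0.20 (adjusted p = 0.013), Tgif1, a transcriptional repressor, by 1.41 ± 0.23 (adjusted p = 0.027), and Cldn5, a tight junction protein of endothelium, by 1.29 ± 0.16 (adjusted p = 0.01). Aldoc, a glycolytic aldolase, and Rtn2, a reticulon, fell to the floor at several times, which makes their differences at these times lower limits (adjusted p = 0.00057 and 0.0026). The median of Ncam1 went from -1.71 to -1.31 with the floor at the 60th percentile. Those of Aldoc and Rtn2 went from -1.79 and -1.11 to -2.12 and -1.69 with the floor at the 20th percentile. Their equal floored values narrow the spread between times, so the adjusted p of both genes can be too small. Blnk, a B cell adaptor, fell by 1.56 ± 0.10 (adjusted p = 0.00057) and was lower by a median of -0.53 on its other probe set. Markers of uterine epithelium, of which Ltf is one, were lower on the same arrays, with list medians between -0.59 and -0.44. Some control probe sets were lower on all 5 too. Among them were 18S RNA at its 3' end by -0.69 to -0.25 and MURINE_b1 by -0.72 to -0.22. The -0.69 of 18S RNA, at 15 h, is a limit from a floored value. The spike-in controls BioB were lower by -0.38 to -0.08, BioC-3 by -0.30 to -0.22, BioDn-3 by -0.23 to -0.13 and BioDn-5 by -0.2 to -0.01. Beta-actin went the other way on its 3', 5' and middle probe sets, by 0.14 to 0.45 on all 5. The controls BioC-5 and CreX lay at -0.09 to 0.15.

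Of 7724 probe sets tested with limma, 69 rose and 139 fell at an adjusted p under 0.05, and 1464 had an unadjusted p under 0.05; with no filter on expression 22 rose and 202 fell. With 6, 12, 15, 18 or 24 h in the place of 0 h as the lone array, limma called 0 probe sets, and 782, 93, 102, 163 and 120 had an unadjusted p under 0.05. The counts changed with each progesterone array left out: 590 without 6 h, 42 without 12 h, 47 without 15 h, 58 without 18 h and 90 without 24 h, of which 205, 41, 47, 58 and 80 were among the 208. Of the 45 named probe sets called, 19 passed in each of these 5 fits, among them those of Acot7, Lrp2, Npl, Sec23b, Pla2g10, Acta1, Nde1, Gstm2, Hdc, Igf1, Abca4, Lifr, Aldoc, Rtn2 and Blnk. Tgfbi, Igfbp3, Smpdl3a, Ncam1 and Ltf passed in 1 of the 5, the fit without 6 h, with adjusted p of up to 0.14, 0.11, 0.11, 0.097 and 0.12 in the others. Mthfd2 did not pass without 12 or 15 h, Slc2a3 without 12, 15 or 24 h, Efnb2 and Tgif1 without 12, 15 or 18 h, and Cldn5 without 12 h, while Atp1b1 passed only without 24 h. The spread in this test is that between times, and the lone 0 h array was assumed to vary like the others. With another array in the lone place, the 0 h array joined the group of 5. It correlated at 0.9335 to 0.9498 with the others, against 0.9554 to 0.99 between progesterone arrays. This distance widens the spread in those fits, so they give no background for the 0 h comparison. Floored values narrow the spread for Aldoc and Rtn2, also with an array left out.

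The second comparison took each time on its own. Among genes above the floor on both arrays, Acot7, Lrp2 and Pla2g10 were in the highest 4 at every time, joined by Mthfd2 from 6 to 15 h and by Acta1 at 18 and 24 h. The lowest genes at 6 h were Slc15a2, a peptide transporter, at -2.00, the phosphatase Ptpn22 at -1.93, Abca4 at -1.74 and Tgif1 at -1.73. At 12 h they were Tgfbi, Clca1, the leptin receptor Lepr and Igfbp3, at -2.42, -2.26, -2.04 and -1.98. At 15 h Tgfbi was followed by Dbp, a clock-controlled transcription factor, at -2.63, the methyltransferase Inmt at -2.56 and the adipocyte hormone Adipoq at -2.53. At 18 h Tgfbi, Inmt, Napsa and Igfbp3 were lowest, at -2.89, -2.61, -2.49 and -2.03. At 24 h the order was Inmt at -3.32, Tgfbi, the aspartic protease Napsa at -2.26 and Adipoq at -2.19. At least 2-fold higher than at 0 h were 109 probe sets at 6 h, 141 at 12 h, 158 at 15 h, 88 at 18 h and 82 at 24 h, and 85, 135, 122, 139 and 107 were at least 2-fold lower. Simulated unchanged arrays sharing 1 reference array gave means of 1.22 to 1.60 and at most 6. Their spread left out the wider pair of 6 and 12 h, so these simulated counts may be too low. The 0 h array was simulated with this spread too, so they cannot exclude a difference of that single array with another cause. Neighbouring progesterone times differed less than each did from 0 h. Between 6 and 12 h 44 probe sets were 2-fold apart, 5 between 12 and 15 h, 7 between 15 and 18 h and 3 between 18 and 24 h. The 6 h array was further from the later ones, with 102, 123 and 142 at 15, 18 and 24 h. The pairs 12 and 18, 12 and 24, and 15 and 24 h gave 19, 36 and 11. Against 0 h, 189 to 280 were 2-fold apart in either direction. No single time had a replicate check, so these counts describe the arrays compared.

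**Figure D1:**
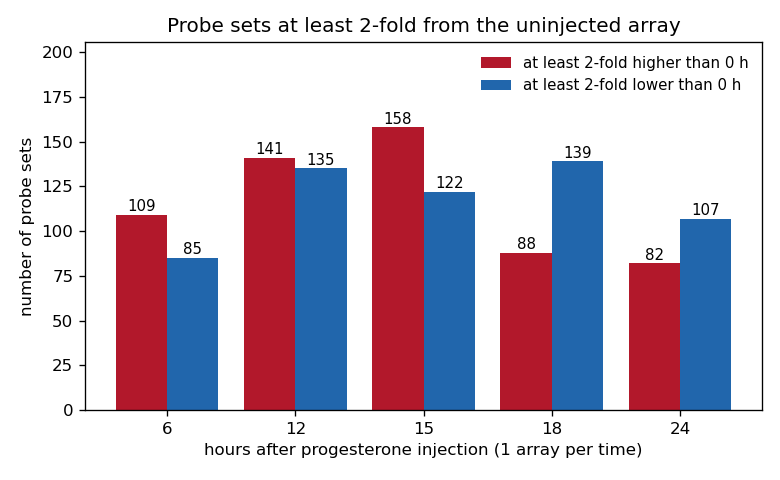
Number of probe sets at least 2-fold higher or lower than on the uninjected array at 6, 12, 15, 18 and 24 h after progesterone (x axis, hours; y axis, probe sets; 1 array per time). Higher probe sets were most numerous at 15 h (158); lower ones were so at 18 h here (139), but at 12 h with quantile normalization (145, against 122 at 18 h).

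The differences from 0 h of any pair of times correlated across probe sets with r between 0.56 (6 and 24 h) and 0.92 (12 and 15 h). Unchanged arrays that share the 0 h array gave 0.50, and part of the excess may come from that array, which cannot be split. Covariances were 0.0833 to 0.174 against 0.0191 in the simulation for 6 and 24 h and for 12 and 15 h. At both 12 and 15 h, 114 probe sets were at least 2-fold higher and 97 lower, against 0.34 and 0.43 in unchanged arrays and 2.89 and 2.14 for independent lists. At both 6 and 24 h, 29 were higher and 40 lower, against 0.40 and 0.44 in unchanged arrays and 1.16 and 1.18 for independent lists. Genes are not independent replicates, and the correlations describe the arrays only.

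By size, 26 probe sets were at least 2-fold higher and 34 at least 2-fold lower at all 5 times, against 0.25 and 0.29 in unchanged arrays. Besides the genes above, the higher ones included Myd88, an adaptor of innate immune receptors, Fzd1, a WNT receptor, and Srm, which makes spermidine, and the lower ones Lama3 and Lamb3, chains of epithelial laminin, and Itgb4, the integrin that binds it; apart from Fzd1 these were chosen after their values were seen. Myd88 did not pass without 12, 15 or 24 h, Srm without 12 or 18 h and Lamb3 without 12 h. Fzd1 rose by 1.35 ± 0.21 (adjusted p = 0.022, but not without 12, 15, 18 or 24 h). Its median went from 1.27 to 0.25 with the floor at the 60th percentile. The simulation gave the 0 h array the spread of neighbouring progesterone times. A difference of that single array with another cause would enter all 5 times, and the simulated counts of this group cannot exclude it.

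An early group was at least 2-fold from 0 h at 6 h and under 1.5-fold at both 18 and 24 h. Sgk1, a kinase induced by steroids, was higher by 2.08 at 6 h, 1.11 at 12 h, 0.55 at 15 h and 0.13 at 24 h, with -0.42 at 18 h. Errfi1, a feedback inhibitor of the EGF receptor, stood at 1.57 at 6 h and 0.37 at 12 h, Lmo7, a LIM domain protein of cell junctions, at 1.57 and 1.35, and Creld2, a protein of the endoplasmic reticulum, at 1.46 and 1.46. Ihh, the hedgehog ligand of uterine epithelium, had differences of 1.42, 1.16, 0.88, 0.34 and 0.51 at 6, 12, 15, 18 and 24 h. Cyp26a1, which degrades retinoic acid, was at the floor at 0 h, higher by at least 2.44 at 6 h and at least 0.71 at 12 h, and at the floor again from 15 h. Its median of 0 went to 0.50 with the floor at the 20th percentile. Marcks, a protein kinase C substrate, was lower at 6 h by -1.38, Ptgr1, a prostaglandin reductase, by -1.38, Cryz, a quinone reductase, by -1.30 and Lum, the matrix proteoglycan lumican, by -1.22, and these 4 lay between -0.31 and 0.33 at 18 and 24 h. The group held 31 higher and 12 lower probe sets, against 0.61 and 0.54 in unchanged arrays, whose spread left out the 0 and 6 h arrays. When the 6 h array was set against the 18 and 24 h arrays in place of 0 h, a comparison chosen after seeing the data, 13 of the 31 and 5 of the 12 were at least 2-fold apart. The definition of the group already fixed the direction of this difference and part of its size.

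A late group was under 1.5-fold at 6 h and at least 2-fold at both 18 and 24 h, and the third comparison fitted a linear trend over hours to all 6 arrays. Col3a1, a fibrillar collagen, rose by 2.32 ± 0.20 per 24 h (SE, adjusted p = 0.018), from 0.44 at 6 h to 2.14 at 24 h. Col1a1 rose by 1.88 ± 0.18 per 24 h (adjusted p = 0.019), Col6a2 by 1.80 ± 0.23 (adjusted p = 0.046) and Col6a3 by 1.66 ± 0.19 (adjusted p = 0.032). A second probe set of Col3a1 rose by 1.22 ± 0.18 (adjusted p = 0.048). Dmpk, a kinase of muscle, rose by 1.76 ± 0.21 per 24 h (adjusted p = 0.032). In the late group without passing the trend test, Aqp4, a water channel, stood at 1.75 and 1.79 at 18 and 24 h (median 0.17 on its other probe set), and Sqle, an enzyme of cholesterol synthesis, at 1.89 and 1.38. Inmt fell by 3.68 ± 0.34 per 24 h (adjusted p = 0.018), Aldh1a1, which makes retinoic acid, by 1.94 ± 0.22 (adjusted p = 0.029) and Krt7, a keratin of epithelium, by 1.51 ± 0.22 (adjusted p = 0.046). The receptor Igf1r fell by 1.31 ± 0.14 per 24 h (adjusted p = 0.029), Bex1 by 1.09 ± 0.14 (adjusted p = 0.046), and Clca1, a secreted protein of epithelium at the floor from 15 h, at an adjusted p of 0.046. Napsa, the cathepsin Ctsf and Lepr were lower at 24 h by -2.26, -1.36 and -1.99 without passing the trend test; Lepr was at the floor at 15 and 18 h. With the floor at the 60th percentile the medians over times of Col3a1, Clca1, Lepr and Ctsf went from 1.44, -2.96, -2.04 and -1.71 to 0.93, -1.86, -0.95 and -1.11. Beside Krt7 and Clca1, epithelium markers stood at -0.44 at 24 h, and beside the collagens smooth muscle markers stood at 0.21.

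The late group held 24 higher and 23 lower probe sets, against 0 in every simulated set of unchanged arrays, whose spread left out the 0 and 6 h arrays. Of these, 14 of the 24 and 12 of the 23 were also at least 2-fold from the 6 h array. The definition of the group already fixed the direction of that difference and part of its size. In the trend test 15 probe sets rose and 9 fell of 7731, and 1254 had an unadjusted p under 0.05; with quantile normalization the split was 5 and 5. Left-out arrays moved the count: with limma it was 0 without 12, 15 or 18 h (1119, 1045 and 929 probe sets at an unadjusted p under 0.05), 1 without 6 h, 52 without 24 h and 147 without 0 h. No named gene of the trend therefore passed without each array in turn. Of the 24 probe sets, 1 was called again without 6 h, 13 without 24 h and 21 without 0 h, and 0 changed sign in any of these fits. Inmt passed in 3 of the 6 such fits, Col3a1, Col1a1, Col6a2, Col6a3, Aldh1a1 and Igf1r in 2, and Dmpk, Bex1, Krt7, Clca1 and the second Col3a1 probe set in 1. None of the 24 probe sets was among the 208 of the first comparison.

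**Figure D2:**
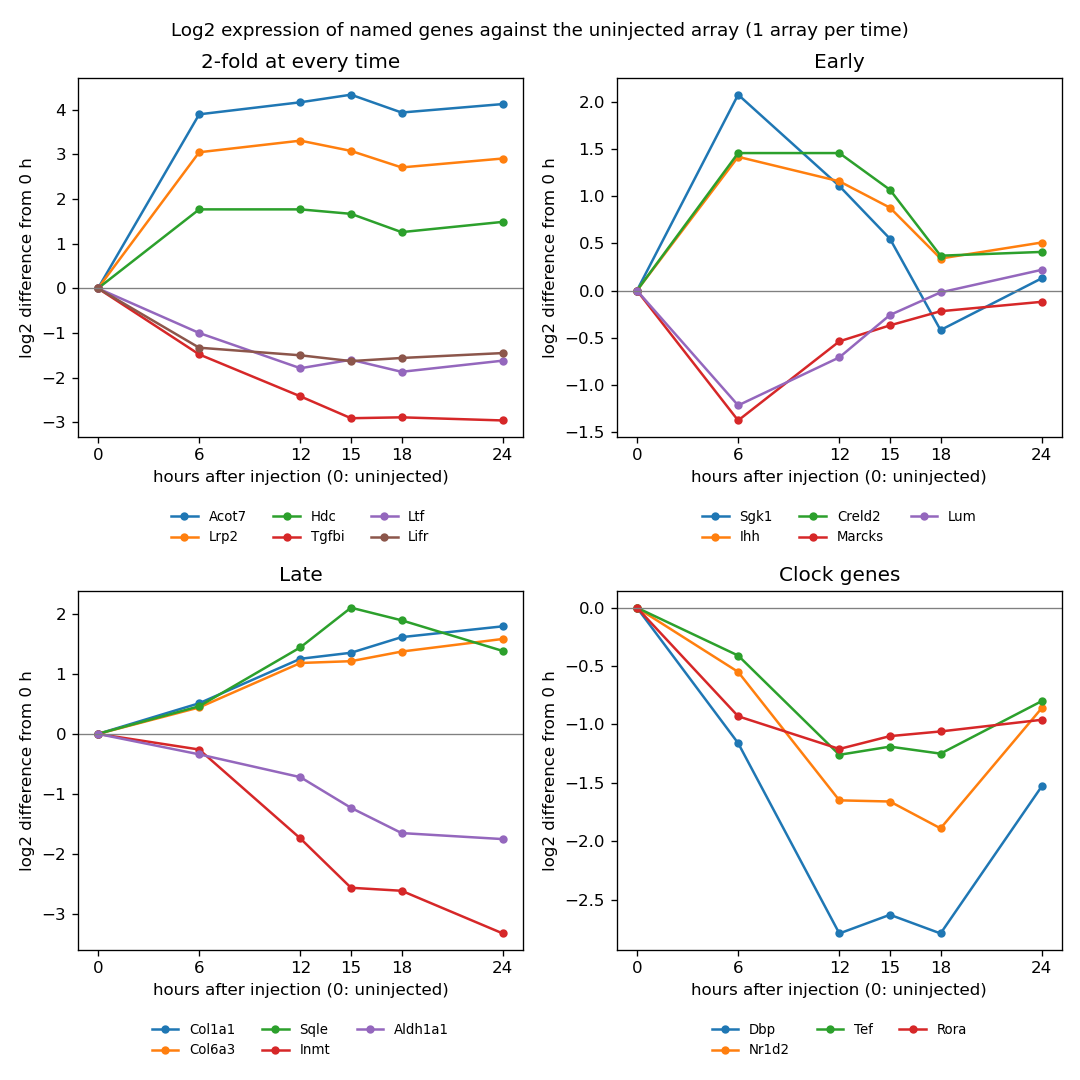
Log2 difference from the uninjected array (y axis) against hours after progesterone (x axis) for genes at least 2-fold from 0 h at every time, early genes, late genes and clock genes, with 1 array per point and lines joining the times. Sgk1 went from 2.08 at 6 h to -0.42 at 18 h while Col1a1 went from 0.51 to 1.79 by 24 h; Dbp lay at the floor at 12 and 18 h, so its -2.79 there is a limit.

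Known progesterone targets of the uterus were higher mainly at 6 h. Their median difference over 37 analysed genes was 0.32 at 6 h, above all but a negligible share of random lists (percentile 100), then 0.16, 0.02, -0.01 and 0.07 at 12, 15, 18 and 24 h. At 6 h 12 of them were at least 2-fold higher, and 5, 4, 4 and 4 at the later times. Lrp2, Hdc and Acod1 rose and Lifr fell over all probe sets tested. Acod1, the enzyme that makes itaconate, was at the floor at 0 h, higher by at least 1.36 at 6 h and 2.57 at 24 h (adjusted p = 0.031, but not without 12, 15, 18 or 24 h). Its median went from 2.14 to 1.03 with the floor at the 60th percentile. Adjusted over the list alone, 7 rose and 1 fell against 0 h, and 1 rose and 1 fell in the trend. Fkbp5, a co-chaperone of steroid receptors, was higher by 1.53 at 6 h and 0.86 at 24 h, and Fst, the activin-binding protein follistatin, at the floor at 0 h, by at least 1.65 and 1.47. The median of Fst over times went from 0.63 to 0 with the floor at the 60th percentile and to 1.43 at the 20th. Gli1, a hedgehog target, had its highest difference, 1.41, at 18 h, and Hoxa10 and Hoxa11, homeobox genes of uterine stroma, stood at 0.83 and 1.28 at 6 h. Gata2, a transcription factor of the uterus, and Il13ra2, an interleukin 13 receptor, both stood at 1.02 at 6 h, the latter as a limit from a floored 0 h value. The median of Il13ra2 was 0.75, or 1.95 with the floor at the 20th percentile. Cebpb went from 0.37 at 6 h to -1.14 at 24 h, and Alox15, a lipoxygenase, from -1.03 to 0.45. The receptors Pgr and Esr1 had medians of -0.31 and -0.61 (adjusted p = 0.36 and 0.054), and the 4 probe sets of Esr1 ran from -0.61 to 0.22. Areg was not among the genes that the annotation used here names. The members came from general knowledge of the uterus, which rests partly on arrays like these, so their direction is not independent evidence, and 25 of the 37 are also in another list.

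Steroid-responsive genes shared with glucocorticoids had a median of 0.19 at 6 h and -0.33 and -0.35 at 15 and 18 h, all outside the central 95% of random lists. With the floor at the 60th percentile the last 2 were -0.15 and -0.19, still outside. Zbtb16, a transcription factor induced by steroids, was higher by 2.09 at 6 h and 0.90 at 24 h (median 0.06 on its other probe set), while Cebpd stood at -1.18 at 18 h and Gadd45b at the floor from 12 h. Lox, which crosslinks collagen, fell by 1.22 ± 0.22 (adjusted p = 0.035, but not without 12, 15, 18 or 24 h). Of 31 genes, 0 rose and 3 fell, against 2 and 5 adjusted over the list alone; in the limma trend 0 passed over all probe sets and 8 fell adjusted over the list alone. Estrogen-responsive genes went both ways, with Ltf and Igfbp3 lower and Igf1 higher, and their medians, -0.09 to 0.05, stayed inside the random range. Of 29, 1 rose and 2 fell, against 4 and 4 adjusted over the list alone, and the trend gave 0 and 1 against 2 and 5. Hedgehog genes had a median of 0.29 at 18 h (percentile 99) and -0.06 to 0.13 otherwise; of 9 genes 0 passed limma in either test over all probe sets, and 1 rose adjusted over the list alone. WNT, BMP and TGF-beta genes had medians of -0.12 to -0.02, with 2 of 38 rising (Fzd1 and Tgfbr3) and 2 falling (Id4 and Rspo1), none of which passed without 12, 15 or 18 h, 3 and 6 adjusted over the list alone, and a trend count of 0 over all and of 1 and 4 over the list alone. Id2 and Id3, targets of BMP signalling, were lower by -1.13 and -1.31 at 18 h. Immediate-early genes were higher at 6 h (median 0.10, or 0.18 with the mean over probe sets of a gene) and lower from 12 h (-0.33 at 18 h). Of 28, 3 fell (Ccn2, Btg1 and Klf6, none of which passed without 12 h), against 1 rising and 4 falling adjusted over the list alone, and 0 in the trend against 4 falling; the transcription factor Myc stood at 1.44 at 6 h. The median of Myc was 0.86, or 0.49 with the floor at the 60th percentile.

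Genes of protein folding and of ribosome assembly were higher together from 6 to 15 h and less so later. Endoplasmic reticulum chaperones and heat shock genes had medians of 0.54, 0.53, 0.55, 0.09 and 0.08 over 37 genes. Manf, a stress-induced protein of the endoplasmic reticulum, was higher by 1.73, 1.88 and 1.65 at 6, 12 and 15 h and by 0.63 at 24 h. The heat shock protein Hsph1 was higher by 1.70 at 6 h. The chaperone Hspa5 (BiP), a further example from outside the naming rule, stood at 1.20 at 6 h. Ddit3, a transcription factor of the stress response, went the other way, to -1.42 at 18 h. Only Hspd1 of the list rose over all probe sets, and not without 12, 15, 18 or 24 h (adjusted p = 0.039 and up to 0.11; 1 and 0, against 1 and 1 adjusted over the list alone), and in the trend 0 passed against 1 falling. Ribosome biogenesis and translation factors had medians of 0.42, 0.45, 0.47, 0.18 and 0.14 over 49 genes. Bysl, Gnl3, Ddx21 and Nop56, all nucleolar, stood at 1.58, 1.44, 1.37 and 1.15 at 6 h and at 0.52, 0.48, 0.43 and 0.63 at 24 h. The medians of Bysl and Gnl3 went from 1.49 and 1.22 to 0.91 and 0.79 with the floor at the 60th percentile. On a second probe set Nop16 rose (adjusted p = 0.037, but not without 12, 15 or 18 h), which the counts do not include. Fbl, Nhp2 and Wdr74 rose, but not without 12, 15, 18 or 24 h, 3 of 49, against 6 adjusted over the list alone, and the trend gave 0 both ways. Cytosolic ribosomal proteins had medians of -0.06 to 0.03 over 25 genes, with the largest absolute median in Rpl22 at -0.59, and 0 passed either limma test over all probe sets or adjusted over the list alone.

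Oxidative phosphorylation and TCA cycle genes had medians of -0.12, 0.20, 0.34, 0.15 and 0.32 over 56 genes, the last 4 above the central 95% of random lists. Cs, citrate synthase, stood at 0.67 at 24 h, Uqcrq at 0.88, and Cox4i1 at -0.49 (0.03 on its other probe set over times), while Cycs, cytochrome c, was at the floor at 0 h and its median went from 1.10 to 0 with the floor at the 60th percentile. Over all probe sets 0 passed limma in either test, and 8 rose in the trend adjusted over the list alone. Cholesterol and fatty acid synthesis genes had medians of -0.19, 0.21, 0.27, 0.12 and 0.16 over 21 genes. At 15 and 18 h they were 0.45 and 0.30 with the floor at the 20th percentile. Idi1, Msmo1 and Sqle, enzymes of the sterol pathway, reached 2.24, 2.02 and 2.10 at 15 h from -0.01, 0.39 and 0.46 at 6 h. The medians over times of Idi1 and Msmo1 went from 1.74 and 1.26 to 0.65 and 0.67 with the floor at the 60th percentile. Scd1, a fatty acid desaturase also counted among the adipocyte markers, stood at -1.80 at 15 h (0.10 on another probe set over times). Over all probe sets 0 passed limma in either test, and in the trend 6 rose and 2 fell adjusted over the list alone. Retinoid, steroid and prostaglandin genes had medians of -0.07 to 0.12 over 28 genes. Hsd11b2, which inactivates glucocorticoids, and Aldh1a2, which makes retinoic acid, rose by 0.73 ± 0.15 and 0.68 ± 0.13 (adjusted p = 0.045 and 0.039, but not without 12, 15, 18 or 24 h). This gave 2 rising and 0 falling against 4 and 3 adjusted over the list alone, and the trend gave 1 and 1 against 2 and 2; Hsd17b11 stood at -1.43 at 12 h. Transport genes had medians of -0.16 to -0.05 over 22 genes, with 2 rising (Atp1b1, Slc2a3) and 1 falling (Slc6a6, but not without 12, 15, 18 or 24 h), 2 and 3 adjusted over the list alone, and 0 and 1 in the trend against 1 and 2.

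Genes of G1/S and DNA replication had a median of -0.16 at 6 h and 0.16 at 12 h over 34 genes, and with 1 probe set per gene 0 passed either limma test, over all probe sets or adjusted over the list alone. A second probe set of the licensing factor Mcm5, with no value from 15 h on and 1 residual degree of freedom, fell (adjusted p = 0.027), but in none of the fits with an array left out, and its first had a median of -0.07. Cdk4 stood at 0.70 at 24 h, Pcna at 0.86 at 15 h, and Mcm3 and Dnmt1, a replication licensing factor and a DNA methyltransferase, at 0.53 and 0.41 at 15 h. Mitosis genes had medians of 0.15 and 0.13 at 18 and 24 h over 18 genes, with 0.34 at 24 h when the floor was at the 20th percentile. Cdk1, the mitotic kinase, was higher by 1.10 at 24 h from a 0 h level of 6.62, close to the floor, Cks1b by 0.67 at 24 h, and Smc4 and Incenp stood at -0.43 and -0.51 at 18 h. Of these genes 0 passed either limma test over all probe sets, and 1 rose in the trend adjusted over the list alone.

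**Figure D3:**
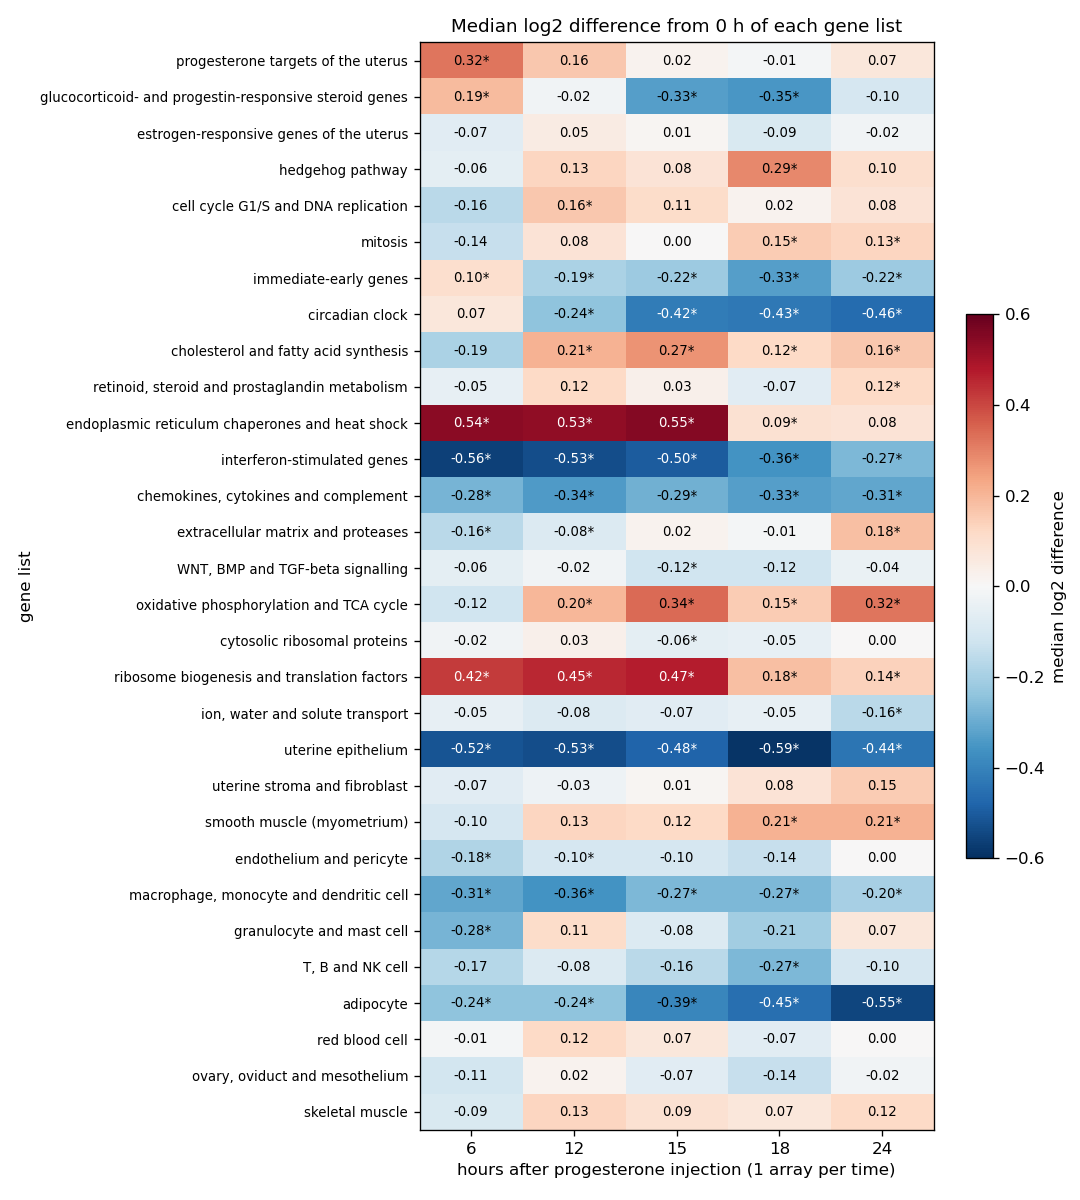
Median log2 difference from the uninjected array of the 30 gene lists (rows) at 6, 12, 15, 18 and 24 h after progesterone (columns, 1 array per time), with red for higher and blue for lower; an asterisk marks medians outside the central 95% of 10000 random lists. Of the 150 medians 72 were outside, from -0.59 for uterine epithelium at 18 h to 0.55 for endoplasmic reticulum chaperones and heat shock at 15 h. The random lists make no allowance for genes that move together, and the times of a list share the 0 h array.

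Among extracellular matrix genes the collagens above rose in the trend, as did Col5a2, and Lox and Fbln1, a basement membrane protein, fell against 0 h, but not without 12, 15, 18 or 24 h. Col5a2, with no value at 24 h, did not pass without 6, 12, 15 or 18 h. The list's median went from -0.16 at 6 h to 0.18 at 24 h over 49 genes, both outside the central 95%. The 6 h value was inside with the floor at the 60th percentile (-0.05), with median scaling (-0.08) and with the mean over probe sets of a gene (-0.14). Against 0 h, 0 rose and 2 fell over all probe sets, and 7 and 7 adjusted over the list alone; in the trend 5 rose and 0 fell, and 19 and 6 adjusted over the list alone. Stroma and fibroblast markers, of which 19 of 34 are in another list, had medians of -0.07 to 0.15. Igf1 and Mme, a membrane protease of stroma, rose and Cxcl12, Fbln1 and Clec3b fell (these 3 not without 12, 15, 18 or 24 h), Mme by 1.12 ± 0.17 (adjusted p = 0.023, but not without 12 or 15 h). Adjusted over the list alone 7 rose and 3 fell, and the trend gave 2 and 0 against 7 and 3. Smooth muscle markers stood at 0.21 at both 18 and 24 h on the same arrays.

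Uterine epithelium markers were lower at every time, with medians of -0.52, -0.53, -0.48, -0.59 and -0.44 over 33 genes, each below all but a negligible share of random lists (percentile 0). Epcam, an adhesion molecule of epithelium, fell by 1.12 ± 0.14 (adjusted p = 0.01), Tspan8, a tetraspanin, by 1.27 ± 0.22 (adjusted p = 0.029, but not without 12, 15, 18 or 24 h), and Krt18, Dsp, Klf5 and Pkp2 fell as well, likewise not without these arrays (adjusted p of up to 0.097, 0.11, 0.11 and 0.11). Krt8 and Krt19, abundant keratins, had medians of -0.29 and -0.54, and the tight junction gene Cldn3 was higher at every time, by 0.26 to 0.56. Over all probe sets 0 rose and 7 fell, against 1 and 18 adjusted over the list alone, and the trend gave 0 and 1 against 0 and 6.

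Circadian clock genes were lower from 12 h, with medians of 0.07, -0.24, -0.42, -0.43 and -0.46 over 21 genes. Dbp was lower by -1.16 at 6 h, -2.63 at 15 h and -1.53 at 24 h, with a floored value at 12 and 18 h. Its median went from -2.63 to -1.69 with the floor at the 60th percentile. Nr1d2, a nuclear receptor of the clock, stood at -0.55, -1.65, -1.66, -1.89 and -0.86, and Tef at -0.41 at 6 h and -1.25 at 18 h. Rora fell by 1.05 ± 0.14 (adjusted p = 0.013, but not without 15 or 18 h). Over all probe sets 0 rose and 1 fell, against 0 and 2 adjusted over the list alone, and 0 passed the limma trend against 3 falling adjusted over the list alone. Adipocyte markers were lower too, with medians of -0.24, -0.24, -0.39, -0.45 and -0.55 over 18 genes. The first 3 of these were -0.63, -0.43 and -0.62 with the floor at the 60th percentile. Adipoq stood at -1.03, -0.96, -2.53, -1.72 and -2.19, Car3, abundant in fat and muscle, at -2.39 at 15 h and the lipase Lipe at -1.37 at 15 h. The lipase Pnpla2 fell, but not without 12, 15, 18 or 24 h; over all probe sets that was 0 and 1, against 0 and 6 adjusted over the list alone, and 0 in the limma trend against 4 falling.

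Red blood cell markers and those of ovary, oviduct and mesothelium, which horns could also carry, gave no median outside the central 95%, unlike the adipocyte markers. Red blood cell markers had medians of -0.07 to 0.12 over 12 genes, with the hemoglobin gene Hba-a1 at -0.43 at 18 h and 0.40 at 15 h. Car2, a carbonic anhydrase also made by other cells, fell by 1.34 ± 0.21 (adjusted p = 0.025, but not without 12, 15 or 18 h), the 1 gene that fell over all probe sets and adjusted over the list alone with 1 probe set per gene; 0 rose, and 0 passed the limma trend. Mkrn1 fell on another probe set (adjusted p = 0.029, but not without 12, 15, 18 or 24 h), with a median of -0.33 on the one used in the list. Ovary, oviduct and mesothelium markers had medians of -0.14 to 0.02 over 15 genes. The oviduct glycoprotein gene Ovgp1 stood at -1.56 at 12 h and Pax8 at -1.10 at 6 h, while Aldh1a2 rose and Rspo1, a WNT agonist, fell, neither without 12, 15 or 18 h. That was 1 and 1 over all probe sets against 1 and 3 adjusted over the list alone, and 0 in the limma trend both ways.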

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

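The groups set without the 0 h array and the epithelium list without shared genes were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group held 1 array. Where no cause is named for a change below, the cause was not tested.

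Scaling left the 2-fold counts and the groups within 1.5 times. A 3-fold threshold, stricter by construction, gave 31, 36, 36, 23 and 25 higher and 9, 28, 32, 25 and 22 lower probe sets at 6, 12, 15, 18 and 24 h, with 11 and 3 sustained, 2 and 0 early, and 5 and 4 late. A floor at the 60th percentile, which hides changes of weakly expressed genes, gave 92 higher at 12 h, 44, 87, 77, 87 and 59 lower at the 5 times, 17 sustained lower, 6 early lower, 12 late lower and 5 lower in the trend. A floor at the 20th percentile gave 19 early lower and 37 higher and 35 lower in the late group. The time with the most lower probe sets moved from 18 h to 12 h with quantile normalization (145, against 122 at 18 h) and median scaling (144, against 122), and to 15 h at 3-fold. With the 6 h array set against 18 and 24 h, 50 probe sets were higher and 34 lower in the early direction, and 50 were lower in the late direction.

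Progesterone arrays against 0 h kept both counts within 1.5 times under either scaling, either floor, the filter on all 6 arrays and eBayes without trend. With no filter 22 rose and 202 fell, which moved the split toward lower. Leaving out 1 progesterone array gave 13 to 256 higher and 29 to 334 lower, with the highest counts without 6 h and the lowest without 12 h, and no call changed sign. The time trend was the least stable count: quantile normalization gave 5 higher and 5 lower, median scaling 7 and 5, ranks of time 8 and 5, log2(hours + 1) 82 and 174, the 5 progesterone arrays alone 79 and 68, no filter 0 and 0 with limma, and the filter on all 6 arrays 14 lower. Leaving out 1 array gave 0 to 79 higher and 0 to 68 lower.

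Of the list medians, 72 lay outside the central 95% of random lists, against 64 to 72 under the alternatives, with 50 to 68 of them shared. Under scaling, floor and probe set choices none of these 72 changed sign, and 4 to 9 of all 150 did; 1, extracellular matrix at 12 h, went to 0 with the floor at the 60th percentile, as did the medians of Cycs and Fst. With the mean of the other 5 arrays as reference, 23 of all 150 changed sign, 8 of them among the 72. These 5 arrays include 0 h, so by construction most of what the progesterone arrays share is removed, but not all. Among the 8 were adipocyte at 6 and 12 h (0.08 and 0.10), chemokines at 6 h (0.04) and endoplasmic reticulum chaperones at 18 h (-0.22). The rest were interferon-stimulated genes and macrophage at 24 h (0.04 and 0.08), and ribosome biogenesis at 18 and 24 h (-0.04 and -0.13). Epithelium medians shrank to -0.1 and -0.01 at 6 and 12 h, inside the central 95%. At 15, 18 and 24 h they were -0.08, -0.25 and -0.12, outside it. Of the named probe sets, 154 of 154 moved by less than the spread between neighbouring times under both scalings, 140 with the lower floor and 95 with the higher, where 28 moved and 31 were no longer analysed, among them those of Abca4, Lifr, Aldoc, Blnk, Rtn2, Ifit1, Epcam and Cd55. On each array 59.4% to 60.9% of probe sets exceeded the floor, and changes below it could not be seen.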

Other observations

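The tests of degraded RNA at 0 h, of each array in the lone place and of other time orders, with or without the 0 h array kept first, were chosen after the results were seen. The other tests were set after the patterns but before the tested values were seen. Interferon, chemokine and macrophage genes were lower at every time. Interferon-stimulated genes had medians of -0.56, -0.53, -0.50, -0.36 and -0.27 at 6, 12, 15, 18 and 24 h over 27 genes, each below the central 95% of random lists, and 25 of the 27 were below 0 h at 6 h. Ifit2, an antiviral protein, fell by 0.93 ± 0.10 (adjusted p = 0.0071), and Ifit1 and Rsad2 fell with values at the floor at several times, Rsad2 not without 12, 15, 18 or 24 h. That was 0 rising and 3 falling over all probe sets, 0 and 12 adjusted over the list alone, and 0 in the limma trend. Floored values narrow the spread between times for Ifit1 and Rsad2, so their calls can look too certain. Psmb9, an immunoproteasome subunit, stood at -1.28 at 6 h and -0.41 at 24 h, and the RNA sensor Ifih1 at -0.87 and -0.60. Chemokines, cytokines and complement genes had medians of -0.34 to -0.28 over 23 genes, -0.17 to -0.02 with the floor at the 20th percentile, and -0.19 and -0.13 at 18 and 24 h with the floor at the 60th. Cd55, a complement inhibitor, fell by 1.08 ± 0.13 (adjusted p = 0.0095), and Cxcl12 and Serping1 fell too (not without 12, 15, 18 or 24 h), 0 and 3 over all probe sets, 1 and 4 adjusted over the list alone, and 0 in the limma trend against 5 falling. Cxcl14 was at the floor from 12 h.

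Macrophage, monocyte and dendritic cell markers had medians of -0.36 to -0.20 over 28 genes, with -0.13 in place of -0.20 at 24 h when the floor was at the 20th percentile. H2-Aa, H2-Eb1 and H2-Ab1, which present antigen as MHC class II, had medians of -0.72, -0.71 and -0.56, and Mpeg1, a macrophage protein, of -0.49; 0 passed limma over all probe sets in either test, and 5 fell against 0 h adjusted over the list alone. Lymphocyte markers had medians of -0.27 to -0.08 over 16 genes with the immunoglobulin joining chain gene Jchain at -0.98 at 6 h. The list median of -0.27 at 18 h was -0.17 and inside the central 95% with the floor at the 60th percentile. With 1 probe set per gene 0 passed either limma test and 2 fell adjusted over the list alone; Blnk, at a median of -0.53 on that probe set, fell on its other one (adjusted p = 0.00057). Granulocyte and mast cell markers had medians of -0.28 to 0.11 over 13 genes. The -0.28, at 6 h, was -0.02 and inside the central 95% with the floor at the 20th or the 60th percentile. Of these genes 1 rose (Hdc) and 1 fell (Ltf, not without 12, 15, 18 or 24 h), 1 and 4 adjusted over the list alone, and 0 in the trend against 1 falling. Endothelium markers had medians of -0.18 to 0 over 27 genes (6 h -0.08 with the floor at the 20th percentile, 12 h -0.17 in place of -0.10 at the 60th), with Cldn5 the 1 gene that fell (not without 12 h), over all probe sets and adjusted over the list alone, and 0 in the limma trend; Vwf, a clotting factor of endothelium, stood at -0.68 at 18 h. Smooth muscle markers had medians of -0.10 at 6 h and of 0.21 at 18 and 24 h over 24 genes, only the last 2 times outside the central 95% (18 h 0.33 with the floor at the 60th percentile), with the contractile protein genes Cnn1 and Des at 0.68 and 0.71 at 24 h; 0 passed limma over all probe sets, and 8 rose in the trend adjusted over the list alone. Of 19 skeletal muscle markers, with medians of -0.09 to 0.13 inside the central 95%, Acta1 rose against 0 h, and Tnni2, a troponin, and Pygm, muscle glycogen phosphorylase, rose in the trend from floored 0 h values (adjusted p = 0.046 and 0.046). That was 1 and 0 against 0 h, over all and adjusted over the list alone, and 2 and 0 in the trend against 3 and 0. Neither trend call held without 6, 12, 15, 18 or 24 h, and the median of Tnni2 went from 1.61 to 0.50 and 2.57 with the floor at the 60th and 20th percentile.

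Lower uterine epithelium markers on all 5 progesterone arrays could reflect a lower share of epithelium in the progesterone pools than in the 0 h pool. Of Krt8, Krt18, Krt19 and Cdh1, 0 of 4 had a median above -0.2, which would have argued against it, yet they spread from -1.03 (Krt18) to -0.25 (Cdh1) and did not shift together, so this stays open. Degraded RNA in the 0 h sample is argued against: the 3' minus 5' differences of beta-actin (0.26) and Gapdh (-0.12) at 0 h lay 0 outside the ranges of the progesterone arrays, 0.19 to 0.33 and -0.15 to -0.05. Without the genes held by another list, the medians of 29 genes were -0.59 to -0.44, and Cldn3, Sox17 and Cldn4 had medians of 0.47, 0 and 0.16. Other technical differences of the 0 h sample or array, an effect of progesterone and the injection itself remain open and untested, since no array separates them. Among the controls, 18S RNA at its 3' end was also lower on the progesterone arrays, by -0.69 (a limit at 15 h) to -0.25. The BioB controls were lower by -0.38 to -0.08, but they are spike-ins and say nothing about the tissue.

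Clock genes, lower at 12 to 18 h, may follow the time of day of tissue collection rather than the hormone. Arntl, Npas2, Clock, Nfil3 and Cry1 were taken beforehand as peaking opposite to Dbp, which was not checked for each of them. Arntl stood at 0.54, 0.60 and 0.41 at 12, 15 and 18 h against 0.17 at 24 h. Of these genes, 1 of 5 (Arntl) was at least 0.3 above both 0 and 24 h. That was fewer than the explanation needed and more than would have argued against it, so time of day and progesterone cannot be told apart for these genes. The list median was lowest at 24 h (-0.46, after -0.24, -0.42 and -0.43 at 12, 15 and 18 h). The list mean was lowest at 18 h (-0.53) and stood at -0.4 at 24 h, where Dbp and Nr1d2 had moved back to -1.53 and -0.86. The list mixes genes taken as opposite in phase, so neither value can decide on a daily return. The clock time of each collection is not given in the sources used here.

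Lower adipocyte markers, with the lowest values of Adipoq, Car3, Scd1 and Lipe at 15 h, could come from different amounts of adherent fat tissue between pools. Of 13 other adipocyte genes, 5 (38.5%) were lower at 15 h than at both 12 and 18 h, between the bounds set for and against this explanation, so it stays open. Thrsp and Fasn, at 10.5 and 10.7 at 0 h among the most abundant of these, stood at -0.85 and -0.39 at 15 h. Of the 18 genes 2 are in another list, and a response of fat cells to progesterone was not tested.

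With each of the 6 arrays in the lone place, 1 gave as many as 208 probe sets, the 0 h array, and the highest other count was 0; 6 placements are too few for a share under 0.05. The other placements kept the distant 0 h array in the larger group, which widens their spread, so their counts are no background for it. Of 100 time orders, 2 gave as many as the 24 probe sets of the linear trend, the real one included. Most of these orders moved the 0 h array, so they mix its distance from the others with the order of time. Of 100 distinct orders that kept the 0 h array first, 3 gave as many as 24, the real one included. That share is under 0.05, yet the order 0, 6, 18, 24, 12 and 15 h gave 37, the highest, and the order 0, 24, 18, 15, 12 and 6 h gave 32 in both sets. The count therefore does not single out the real order of times, and in limma it fell to 0 without 12, 15 or 18 h.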
